A study of Homo sapiens with 2 samples.

How the data were processed

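The series holds 2 microarrays, 1 of HCC827 cells and 1 of HCC827/GR cells, hybridised with Cy3-labelled material from total RNA in a single colour, per the labels' protocols. The authors deposited 1 scanner output file per array. Per the file headers, spot intensities were extracted with Agilent Feature Extraction 11.5.1.1, while the submitters' processing notes name Agilent Feature Extraction 10.7. The processed intensity is background-subtracted, spatially detrended and floored above 0 by that program, per the file headers, and is not scaled between arrays. The deposited files also hold the median spot intensity, the local background intensity, and flags for saturation, non-uniform or outlying spots, and spots well above background. No aligner or counter applies to these data. The headers place both arrays on 1 slide at different positions, so array position and cell line cannot be told apart.

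Each array has 180880 spots, of which 175906 are not controls and cover probes printed 2 times (49541 probes) or 3 times (25608 probes). Flagged spots were left out per array, and the 18 probes that lost all spots on an array were dropped, which left 75131. Spots of 1 probe were averaged as log2 intensity. Each array's 75th percentile over these probes was then subtracted, because most of the probes (57.7%) were detected on both arrays. A probe was called detected on an array when all its kept spots were well above background, and not detected when none was. No spot was saturated. Differences are HCC827/GR minus HCC827 on the log2 scale. For a probe detected on 1 array only, the lower bound of its fold was taken against the higher of its own signal and the lowest signal of any detected probe on the other array.

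There was 1 array per group, so no test between the cell lines was possible and no p-value is given. Spot standard deviations and standard errors describe spots of 1 array and leave out the spread between cultures, RNA extractions, labellings and arrays. Probes are described by size, with 2-fold as the threshold. A class of probes was set against 10000 random lists of the same size, matched on mean signal in 20 bins, which describes these 2 arrays only.

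The files pair probes with identifiers and, outside some control probes, with no gene symbols, and the reference table used here lists no probe identifiers. Of the 927 genes in the 43 gene lists fixed before the data were examined, 2 had a probe named for them, the control probes of PGK1 and GAPDH. The lists, CDK14 (PFTK1, the gene of the series title), other genes of interest and chromosome windows were therefore not analysed here. The rule for named genes, fixed before the data were examined, was CDK14, a set of marker genes, the members of each list with the largest differences, the 12 genes with the largest difference each way, the 5 with the highest bound each way, and the leading non-coding RNAs. It was applied to probes without regard to coding status, and identifiers are printed for the first 2 each way. PGK1 and GAPDH were in the fixed lists. Classes were read from the probe names (A_, p, p with _v4, RNS, imsncRNA, snoRNA_scaRNA, snRNA, tRNA, rRNA, and RNA with a number only) after the files had been seen. The meaning of RNS and imsncRNA, and which A_ and p probes are coding, is not given in the sources used here.

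The alternatives fixed before the data were examined were normexp background correction with an offset of 50, quantile normalization, cyclic loess, the median or the 75th percentile of detected probes, no filter or a stricter filter on dim probes, and leaving out spots flagged on either array. Normexp was run on the median spot intensity. Taking the median over a gene's probes was not run, since probes could not be joined into genes. Scaling to the E1A control probes, detection by any spot, and separation of all spots were chosen after seeing the data. Normalizations used limma 3.58.1 in R 4.3.3, and the rest Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The procedure was tested on data simulated for this comparison over 43332 probes. All of the 100 simulated 4-fold changes passed the 2-fold threshold, 99 of 100 simulated 3-fold changes did, and 0.409% of unchanged probes did from spot noise. A shift of 0.3 given to the 76 tRNA probes came back as 0.31. That is larger than the shifts found against probes of like signal, 0.14 for tRNA and 0.07 for snoRNA_scaRNA. Recovery at those sizes, and of changes under 3-fold, was not tested.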

Results

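Expression was profiled by 1-colour microarray in HCC827, a human non-small-cell lung cancer line with mutant EGFR, and in HCC827/GR, a line derived from it. The derived line had been kept in stepwise rising gefitinib, an inhibitor of the EGFR kinase, from 0.1 to 5 µM over 1 year. The array carried probes for long non-coding RNAs and mRNAs. The single comparison the design implies is HCC827/GR against HCC827, which asks how expression differed between resistant and parental cells. Each line was represented by 1 array, so all differences below compare these 2 hybridisations and carry no replicate error. On the HCC827 array 62.9% of the non-control spots were well above background, and on the HCC827/GR array 60.3%. Median local background was 44 intensity units on the HCC827 array and 47 on the HCC827/GR array.

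PGK1, the glycolytic enzyme phosphoglycerate kinase, was higher in HCC827/GR on both human control probes named for it. GAPDH, another glycolytic enzyme that is widely used as a reference gene, differed less on its human probes. The PGK1 probe with suffix 3 read 5.24 ± 0.06 in HCC827 and 6.44 ± 0.05 in HCC827/GR (scaled log2 signal, SD of 10 spots on each array). This is a difference of 1.20 ± 0.03 (spot SE), or 2.29-fold. The PGK1 probe with suffix 5 read 2.04 ± 0.05 in HCC827 and 3.51 ± 0.07 in HCC827/GR (SD of 10 spots), a difference of 1.48 ± 0.03 (spot SE), or 2.78-fold. For both PGK1 probes every HCC827/GR spot lay above every HCC827 spot. The GAPDH probe with suffix 3 differed by -0.02 ± 0.03 (spot SE, 9 and 7 spots), which is within its spot error. The GAPDH probe with suffix 5 differed by 0.33 ± 0.11 (spot SE, 10 spots each). Its HCC827 spots had an SD of 0.33 and overlapped those of HCC827/GR. PGK1 exceeded GAPDH in its difference by 1.21 ± 0.04 for suffix 3 and by 1.15 ± 0.11 for suffix 5 (spot SE). Among 978 probes within 1 log2 unit of the signal of the PGK1 suffix 3 probe, 6 (0.613%) were higher in HCC827/GR by as much or more. Among 6222 probes near the signal of the suffix 5 probe, 79 (1.27%) were.

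**Figure D1:**
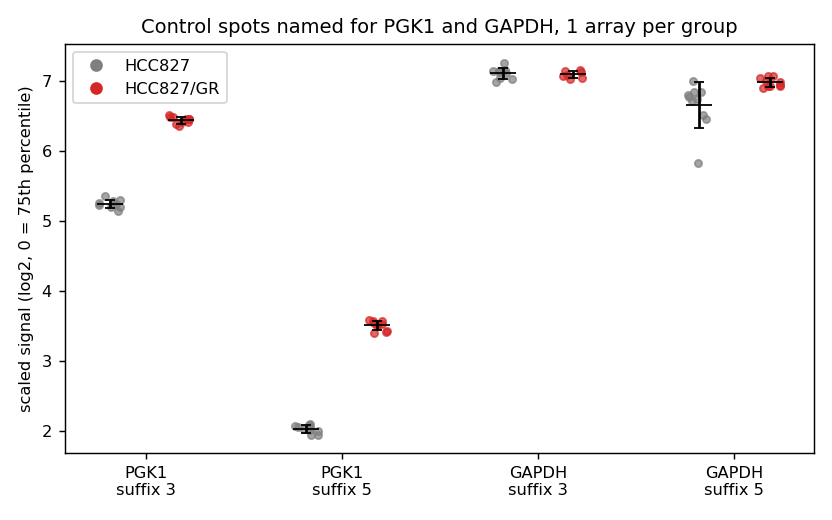
Scaled signal (log2, 0 is each array's 75th percentile) of single control spots named for PGK1 and GAPDH, with HCC827 in grey and HCC827/GR in red; black marks are the mean and SD over spots of 1 array. Both human PGK1 probes are separated between the arrays (differences of 1.20 and 1.48), and the human GAPDH probes are not.

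The E1A control probes, which detect adenoviral transcripts added as a spike-in in the Agilent workflow, differed between the arrays by little, and other control probes by more. Of 10 such probes, 7 were well above background on every spot. Their differences after scaling ran from -0.25 to 0.04, with a median of -0.02. Of 18 control probes with DCP names, 17 were well above background on every spot. Their differences ran from -0.23 to 0.70, with a median of -0.06; for 2 of them all HCC827/GR spots lay above all HCC827 spots and for 5 the reverse held.

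Across all probes the lines were similar, with a small part of the probes differing by 2-fold or more in either direction. Of 75131 non-control probes, 43332 were detected on both arrays, and their signals correlated across probes with Pearson's r of 0.971 and Spearman's rho of 0.963 (probes are not independent replicates). Of the detected probes 40343 (93.1%) lay within 2-fold. The probes at least 2-fold higher in HCC827/GR numbered 1549 (3.57%), and those at least 2-fold lower numbered 1440 (3.32%). At 4-fold the counts were 266 higher and 197 lower, and at 16-fold they were 20 higher and 8 lower. The larger side of the 2-fold counts turned with the scaling: taking the 75th percentile over detected probes gave 1364 higher and 1650 lower. Within 1 array, paired spots of the same probe lay 2-fold or more apart for 1.24% of the probes in HCC827 and 1.12% in HCC827/GR. For 1543 of the higher and 1429 of the lower probes, all spots of one array lay beyond all spots of the other. This adds little, since the median spot SD was 0.08 on each array. Selecting differences of 2-fold or more then nearly fixes the separation.

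**Figure D2:**
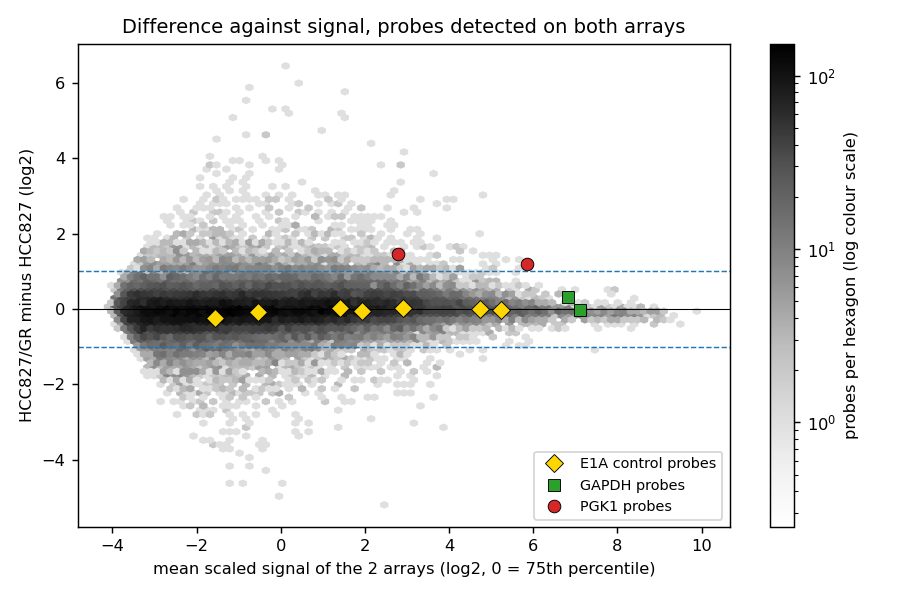
Difference HCC827/GR minus HCC827 (log2) against mean scaled signal (log2) for the 43332 probes detected on both arrays, as the number of probes per hexagon; dashed lines mark 2-fold. The 7 E1A control probes and the GAPDH probes lie between the lines and both PGK1 probes lie above the upper one.

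The largest differences on both arrays reached 87.8-fold higher and 36.7-fold lower in HCC827/GR. Probe A_23_P23048 was higher by 6.46 ± 0.21 and probe A_23_P314755 by 6.01 ± 0.21 on the log2 scale (spot SE, 2 spots per array). Probe p5993 differed by -5.20 ± 0.36 and probe p34144_v4 by -4.95 ± 0.11 (spot SE, 3 spots per array). With normexp background correction the differences were 5.16 for A_23_P23048, 5.10 for A_23_P314755, -5.03 for p5993 and -4.13 for p34144_v4. The 12 leading probes higher in HCC827/GR spanned 27.4-fold to 87.8-fold, and all 12 had A_ names, the form used for Agilent catalogue probes. The 12 leading probes lower in HCC827/GR spanned 13.2-fold to 36.7-fold, and 9 of them had p names, with or without _v4. Among these 9 was a pair of consecutive numbers, which need not read separate transcripts. Of all 43332 detected probes, 24044 had A_ names and 17432 had p names.

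Some probes were detected on 1 array only. In HCC827 alone 1351 probes were detected, and in HCC827/GR alone 425. As a lower bound, 327 of the former and 208 of the latter differed by at least 2-fold. The 5 highest bounds in HCC827/GR ran from at least 124-fold higher to at least 240-fold higher. The 5 highest bounds in HCC827 ran from at least 37.8-fold to at least 240-fold, with HCC827/GR the lower. They included a pair of consecutive p numbers, which need not read separate transcripts. A further 6738 probes had mixed spots on at least 1 array, and 23285 probes were not detected on either.

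By probe name, tRNA and snoRNA_scaRNA probes were slightly higher in HCC827/GR than probes of like signal, though not under every alternative, and probes with p names were slightly lower. Classes are compared with probes of like signal because the median over all detected probes, -0.02 here, ran from -0.08 to 0.04 over the scalings tried, which can turn the sign of a class median as small as that of snoRNA_scaRNA or A_23. Transfer RNAs carry amino acids to the ribosome, and small nucleolar and small Cajal body RNAs guide the modification of ribosomal and spliceosomal RNA. The 76 tRNA probes detected on both arrays had a median difference of 0.13 (1.096-fold), above 99.99% of random lists matched on signal; 44 of the 76 were above 0 and 1 reached 2-fold. That probe, higher by 1.15, had an SD of 1.31 between its HCC827 spots. With a stricter filter on dim probes the shift of the tRNA probes against probes of like signal was 0.08, inside the central 95% of random lists (percentile 96.3). The 244 snoRNA_scaRNA probes had a median of 0.05, above 99.3% of random lists, with 2 probes at least 2-fold higher and 1 lower. The largest of these, at 2.59-fold higher, had spot SDs of 0.01 in HCC827 and 0.02 in HCC827/GR, while the other higher one, at 2.45-fold, had an SD of 0.87 between its HCC827 spots. The shift of the snoRNA_scaRNA probes lay inside the central 95% of random lists under cyclic loess (percentile 96.8), quantile normalization (percentile 97.1) and the stricter filter (percentile 81.95). Genes for tRNAs and snoRNAs have close copies, so a probe can read several of them. The random lists hold unrelated probes, so for a class whose probes read shared transcripts their range is too narrow and the percentile overstates how far the class stands out.

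The medians of the snRNA, rRNA, RNS and imsncRNA probes and of those named by RNA and a number only lay within the central 95% of random lists. The 66 probes for snRNA, the RNA part of the spliceosome, had a median of -0.10 (percentile 17.98 of random lists), with 1 probe at least 2-fold higher and 4 lower, the lowest by 3.11-fold. Spots of these probes differed within the HCC827 array, with SDs of 0.80 for the higher probe and from 0.07 to 0.57 for the lower ones. The 11 rRNA probes had a median of -0.02 (percentile 58.9) and none reached 2-fold, with differences from -0.43 to 0.29. They were among the brightest, with a median scaled signal of 6.71 in HCC827. The 16 probes named by RNA and a number only had a median of 0.01 (percentile 68.3) and none at 2-fold. The 833 RNS probes had a median of -0.05 (percentile 13.8), with 8 higher and 9 lower by 2-fold. Under the stricter filter on dim probes their shift against probes of like signal was -0.05, below the central 95% of random lists (percentile 0.9). The 607 imsncRNA probes had a median of -0.03 (percentile 75.3), with 14 higher and 8 lower. Of 5 vault RNA probes 2 were detected on both arrays, with differences of -0.48 and 0.99. The single detected ribozyme probe differed by -0.05, and the single SRpRNA probe was not detected on both arrays.

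The large classes were split by name. The 24044 detected A_ probes had 1048 higher (4.36%) and 819 lower (3.41%) by 2-fold, and the 17432 detected p probes 475 higher (2.72%) and 599 lower (3.44%). These counts were not matched on signal, and the p probes were dimmer. Their median scaled signal in HCC827 was -1.28, against 0.28 for A_ probes, and the balance of higher and lower probes varied with signal. Medians were 0.04 for A_23, 0.09 for A_24 and 0.07 for A_32 probes, each above all 10000 random lists matched on signal. They were 0.00 for A_19 (percentile 83.8), -0.01 for A_33 (percentile 95.8) and -0.05 for A_21 (percentile 4.39, and 2.45 with normexp background correction, below the central 95%). The 13164 p probes without _v4 had a median of -0.08 and the 4268 with _v4 a median of -0.08, each below all 10000 random lists. Their random ranges are also too narrow, since differences of consecutive p numbers correlated across probes with r of 0.342. All of these medians were smaller in size than the 0.091 by which the scaling factors of the arrays differed. That difference had already been subtracted, and a constant added to an array does not change the place of a class among the random lists. The lists were drawn from all 43332 detected probes, most of which had A_ or p names. A_ classes above and p classes below the lists are therefore not separate results. Whether A_ probes read shared transcripts was not tested.

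**Figure D3:**
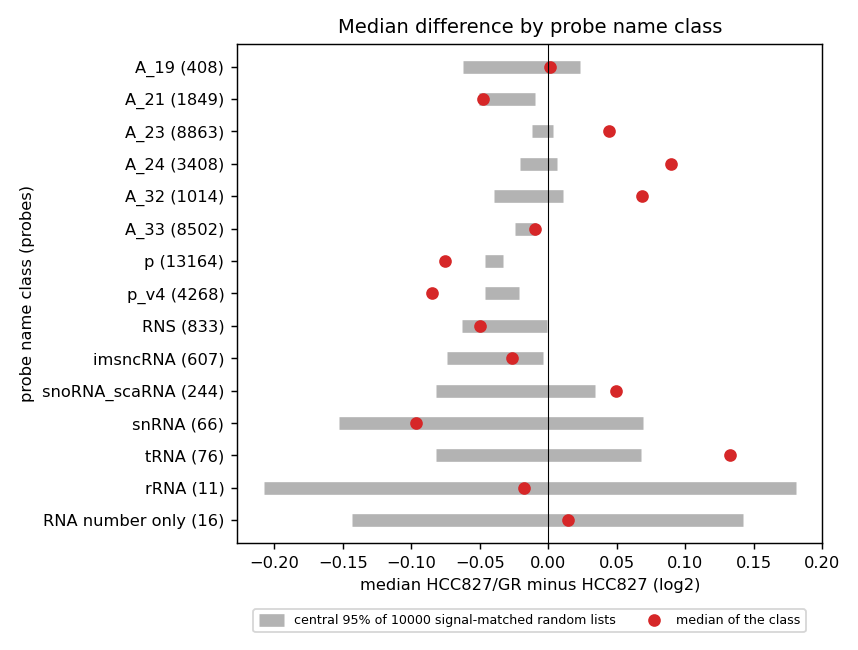
Median difference HCC827/GR minus HCC827 (log2) of each probe name class, with its number of probes detected on both arrays (red points), and the central 95% of 10000 random lists of the same size and signal (grey bars). A_23, A_24, A_32, snoRNA_scaRNA and tRNA lie above their bars and both p classes below.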

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

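The tests of explanations in this part were chosen after the results were seen, except the test with 1 signal limit for both arrays, which was written down before.

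Some control probes named for mouse, rat or ERCC sequences gave signal well above background on every kept spot of both arrays. They were not part of the main comparison. Signal at the rodent probes does not show that rodent RNA was present, since both arrays carried material from human cells. Mouse-PGK1_3 and Rat-PGK1_3 had 0 spots well above background on either array. The rodent PGK1 probes with suffix 5 were higher in HCC827/GR, Mouse-PGK1_5 by 1.88 and Rat-PGK1_5 by 1.67 on the log2 scale. The human PGK1 probe with suffix 5 moved in the same direction, by 1.48. The rodent GAPDH probes differed by 0.21 for Mouse-GAPDH_3, 0.0035 for Mouse-GAPDH_5, -0.50 for Rat-GAPDH_3 and 0.23 for Rat-GAPDH_5. All HCC827 spots lay above all HCC827/GR spots for Rat-GAPDH_3, and the reverse held for Rat-GAPDH_5. Spots of the mouse GAPDH probes overlapped. Of 12 ERCC probes, 2 were lit on both arrays and they differed little, ERCC-00012_90 by -0.050 and ERCC-00043_129 by -0.033; the others had 0 spots well above background.

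The higher PGK1 signal in HCC827/GR was weighed against technical explanations. A scaling error would shift the E1A control probes by about as much, and their median difference was -0.017. Degraded RNA or shorter labelled fragments would shift the GAPDH probe of the same suffix alike if suffixes mark like positions in both transcripts. The sources used here do not give the meaning of the suffixes. PGK1 exceeded GAPDH by at least 1.15 on the log2 scale, which therefore cannot exclude this explanation. The GAPDH probes were also brighter in HCC827 (scaled 7.11 and 6.65, against 5.24 and 2.04 for PGK1), and compression of bright signals was not tested. The human suffix 5 probes did exceed the human suffix 3 probes in difference for both genes, by 0.28 for PGK1 and 0.34 for GAPDH. A difference in fragment length between the arrays could also give this. The rodent GAPDH probes were split. In rat, suffix 5 had the higher difference (0.23, against -0.50 for suffix 3), and in mouse suffix 3 did (0.21, against 0.0035 for suffix 5). A difference between the lines, between single cultures or between labellings of these genes remains open, since each line has 1 array.

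More probes were detected in HCC827 alone than in HCC827/GR alone, 1351 against 425, a ratio of 3.18. At high signal (scaled 1.39 to 5.24 in HCC827), a dimmer HCC827/GR array is argued against by the E1A control probes. Before scaling they were brighter on it by 0.03 to 0.13 at these signals. Over all 7 E1A probes the median was 0.074. At lower signal they did not argue against dimming. E1A_r60_a20 (scaled -0.50) differed by 0.012, and the dimmest, E1A_r60_a107 (scaled -1.43), was dimmer in HCC827/GR, by -0.157. Near the detection limit these probes cannot decide. Control probes with only part of their spots well above background on an array had fewer such spots in HCC827/GR. The counts were 51 of 58 against 60 of 60 (E1A_r60_a135), 0 of 60 against 3 of 57 (E1A_r60_a104), and 10 of 37 against 32 of 39 (ETG10_234183). Their signals before scaling differed by 0.03, -0.53 and -0.20. With 1 signal limit for both arrays the ratio was 1.58 (95% interval 1.48 to 1.69, counting error only), with 2206 probes above it in HCC827 alone and 1398 in HCC827/GR alone. The limit of 1.5 set for this test lies inside that interval. The lowest signal of a detected probe was higher in HCC827/GR (scaled -4.10, against -4.29 in HCC827). Detection limits were thus unequal, and with 1 limit the ratio was lower than 3.18. That limit also counted other probes, so how much of the gap came from unequal limits is not known. For the ratio that remained, higher background or dimmer weak signal on the HCC827/GR array and a difference in weakly expressed transcripts cannot be told apart.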

How the results depend on the processing

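With 1 array per line no replicate could be left out, and no setting says how far a second culture would differ. Counts of probes moved with the filter on dim probes and with normexp. With normexp, which compresses dim signals, 923 probes were higher and 694 lower by 2-fold. Normexp was also run on the median spot intensity in place of the processed intensity, so the effects of these 2 changes cannot be told apart. The counts were 3274 and 3905 without a filter on dim probes, and 789 and 491 with the stricter filter, which tests fewer probes. Under the other settings they stayed within 1.5 times the reported counts, at 1364 to 1766 higher and 1242 to 1755 lower. Among these settings, the count of probes with separated spots (1543 and 1429) was nearly fixed by the 2-fold selection. Higher calls outnumbered lower ones except with no filter and with the 75th percentile over detected probes. The PGK1 differences ran from 1.14 to 1.26 (suffix 3) and from 1.39 to 1.54 (suffix 5), so both stayed above 2-fold under every scaling. With normexp on the median spot intensity, the differences of 3 of the 4 probes named by identifier shrank by more than their spot SD. They became 5.16, 5.10 and -4.13. The tRNA shift against signal-matched probes fell inside the random range under the stricter filter (0.0786, percentile 96.3). The snoRNA_scaRNA shift did so under cyclic loess (0.0534, percentile 96.8), quantile normalization (0.0554, percentile 97.1) and the stricter filter (0.0339, percentile 81.95). A shift left the range for A_21 with normexp (-0.0120, percentile 2.45) and for RNS with the stricter filter (-0.0527, percentile 0.9). The other 134 class values kept their side of the range. Some of these could not do otherwise. Scaling to the median or the 75th percentile of detected probes, or to the E1A probes, subtracts a constant per array. Such a step leaves a shift against signal-matched probes unchanged, apart from the random draw of lists. No paired analysis was possible because the labels give no replicate numbers and each line has 1 array. Scanner flags found no saturated spot, but compression of bright signals was not tested, and below the detection limit only bounds can be given.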

Other observations

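The tests in this part on consecutive numbers were chosen after the pattern was seen in the data, though the bounds for array position and signal level were written before those values were computed.

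Several groups of probes with neighbouring p numbers differed together. Counting runs of at least 4 detected probes, all 2-fold or more in the same direction and with number steps of at most 3, there were 10 runs higher in HCC827/GR and 3 lower, 66 probes in all. The longest held 10 probes with a median of 4.78-fold higher (3.46-fold to 5.74-fold). A run of 6 probes had a median of 9.65-fold higher, from a scaled signal of -2.81 in HCC827 to 0.28 in HCC827/GR. The steepest run that was lower held 5 probes with a median of 12-fold lower (11-fold to 17.2-fold). No more than 2 runs of this length arose in any of 1000 shuffled orders. The targets of these probes are open, since the files give them no gene symbol.

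Over all 9432 pairs of consecutive p numbers the differences correlated across probes with r of 0.342 (rho 0.262), against a highest r of 0.030 in the shuffled orders. Position on the array is argued against by pairs whose spots all lay at least 100 rows apart, where r was 0.299. A shared signal level is argued against by r of 0.341 after cyclic loess and removal of each signal bin's median. The correlation declined with the distance in number, to 0.228 at 2, 0.151 at 3, 0.099 at 5 and 0.027 at 10. A candidate explanation is that neighbouring numbers read the same or overlapping transcripts, which the decline to 0.027 allows. Whether separate transcripts of one locus changed together was not tested.

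The balance of higher and lower probes varied over 10 groups of mean signal. In the dimmest group 72 probes were higher and 62 lower by 2-fold, with a median difference of -0.05. In the second the counts were 140 and 249 (median -0.09), in the ninth 166 and 70 (median 0.06), and in the brightest 94 and 35 (median 0.0089).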
